A study of Mus musculus with 8 samples.

How the data were processed

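Total RNA was taken from 20 embryos per sample at the 2-cell stage, and biotin-labelled cRNA was made with a small sample labelling assay of Affymetrix, per the labels' protocols. The labels give 4 wild type and 4 Brg1 mutant samples. They call the samples biological replicates, and beyond that nothing in them speaks of separate animals or collections, so the p-values measure the spread between these samples.

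The deposited values were array intensities, 1 MAS5 signal per probe set on a linear scale, per the submitters' processing notes. The MAS5 version is not given in the sources used here. The 2% trimmed mean was 150 on all 8 arrays and differed from their median by at most 0.000162%, so no further scaling was done. No pair of arrays held identical values. The number of arrays limits the precision.

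Signals under 1 were set to 1 and log2 was taken. After 64 control probe sets were set aside, 45037 remained, and the 22518 in the upper 50% by mean log2 signal over all 8 samples were tested, which corresponds to a mean log2 signal of at least 5.25. Mutant and wild type samples were compared with limma 3.58.1 (lmFit, eBayes with an intensity trend, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. Errors beside log2 changes are standard errors of the fit. A fold is 2 to the power of the log2 change. Log2 changes of dim probe sets are uncertain. A bound on background was therefore set per array at the 95th percentile of 27 control probe sets for Bacillus transcripts, and a gene under it on all arrays of a group is given as "at least" the mean of the brighter group over the dimmer group's bound. This bound was chosen after the data were seen.

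Gene symbols came from the platform annotation: 34945 probe sets had 1 symbol, 932 had several and 9160 had none. Of the gene identifiers, 34741 matched the RefSeq table of GRCm38.p6, which changed 0 symbols. That table served only for names, and no coordinates are given. A gene was represented by its tested probe set with the highest mean log2 signal. Where other tested probe sets of a gene are not named, they are counted in the text.

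The lists fixed for testing covered BAF and PBAF subunits, other chromatin remodellers, histone and DNA modifying enzymes, early 2-cell transcripts, ribosome biogenesis, cytosolic ribosomal proteins, translation factors, the proteasome, pre-mRNA splicing, the RNA polymerase II machinery, oocyte and maternal-effect transcripts, mRNA deadenylation and decay, mitosis, DNA replication, p53 targets and apoptosis, heat shock and the unfolded protein response, pluripotency and early lineage, oxidative phosphorylation, glycolysis and pyruvate use, histones and imprinted genes, with 4 marker lists for granulosa and cumulus cells, oviduct epithelium, sperm, and blood and leukocytes. All 25 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01 over 11934 genes and adjusted over the lists. With the correlation estimated from the data, 0 of the 25 lists passed (adjusted p between 0.402 and 0.941). Fry, which asks whether a list's genes move one way without comparing them with other genes, passed 9: mRNA deadenylation and decay, BAF and PBAF subunits, the RNA polymerase II machinery, p53 targets and apoptosis, histone and DNA modifying enzymes, DNA replication, imprinted genes, mitosis, and blood and leukocyte markers (fry adjusted p from 0.00319 to 0.0347).

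The genes named are the 12 with the largest rise and the 12 with the largest fall among genes that passed, had a probe set with 1 symbol and a name not ending in _x_at, and had every mutant sample beyond every wild type sample. To these were added Smarca4, Smarca2, the 4 members of each list with the smallest adjusted p, and Pou5f1, Hspa1b, Eif1ax, Zscan4c, Zscan4d, Nlrp5, Zp3 and Dppa3. The groups, tests, lists, naming rule and first set of alternatives were fixed before the data were examined.

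Alternatives were quantile normalization, centring on the median or the 75th percentile, no filter or the upper 30%, a pseudocount of 12.5, no intensity trend, array weights, the replicate number as a block, removal of probe sets with names ending in _x_at or _s_at, the mean of a gene's probe sets, an estimated correlation, and each sample left out in turn. Fits without mutant replicates 3 and 4, and without mutant replicates 1 and 2, were added after the data were seen, for lists also with an estimated correlation. Array measures were compared with exact permutation tests over 70 assignments, whose smallest two-sided p is 0.0286.

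The fit was tested on simulated data for the mutant against wild type comparison, with 200 changed probe sets among 22518 fitted. With the spread pooled over both groups, 40 of 79 changes of 2 log2 units (50.6%) and 4 of 90 of 1 log2 unit (4.44%) were recovered, and 4.35% of calls were false. With the wild type spread, 88.2% and 29.3% were recovered and 2.86% of calls were false. A list shifted by -0.5 was called, and 0 other lists were. The noise was simulated independently for each probe set and array, with the same spread in both groups. It lacks the correlation within the real lists, estimated at up to 0.667, and the differences among the real mutant arrays. The simulated shares of false calls therefore need not hold for the real data. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.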

Results

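Gene expression was measured in mouse embryos at the 2-cell stage, the stage at which transcription from the embryo's own genome begins in earnest in this species. The series title ties the study to BRG1, the ATPase of BAF-type chromatin remodelling complexes encoded by Smarca4, and to activation of the zygotic genome. Total RNA of 20 embryos was pooled for each sample, and 4 wild type samples were compared with 4 samples labelled Brg1 mutant. Each sample was read on an Affymetrix mouse array with 45101 probe sets, of which 22518 entered the tests. All 8 arrays had been scaled to a trimmed mean signal of 150, and their median signals ran from 36.3 to 47.6. Each sample was described as a biological replicate, and the number of arrays limits the precision of every value below.

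On the brighter of 2 Smarca4 probe sets, signal was lower in all 4 mutant samples than in any wild type sample. The signal of this brighter Smarca4 (BRG1) probe set was 675 ± 83.0 in wild type embryos (SD, n = 4) and 288 ± 76.9 in Brg1 mutants (SD, n = 4), which is 2.39-fold lower (log2 change -1.26, SE 0.249, limma adjusted p = 0.0211). The wild type samples read 796, 632.1, 612.1 and 660.6, and the mutant samples read 387.5, 200.9, 273 and 291.3. The other Smarca4 probe set read 253 ± 44.9 and 277 ± 127 (SD, n = 4 each) and did not pass the test (log2 change 0.04, limma adjusted p = 0.963). The sources used here do not say which part of the transcript was deleted or which part each probe set reads, so the unaltered probe set checks nothing about the labels. Smarca2, which encodes the related ATPase BRM, did not pass the test (log2 change 0.10, limma adjusted p = 0.891), with signals of 1122 ± 273 in wild type and 1288 ± 608 in mutant samples (SD, n = 4 each). As the groups did not overlap on the brighter probe set, its change could not turn direction when each sample was left out in turn. It lost the call in 6 of these 8 fits, with a limma adjusted p of 0.0834, 0.0526, 0.0630 and 0.0696 without wild type replicates 1, 2, 3 and 4 and of 0.0586 and 0.0555 without mutant replicates 3 and 4.

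**Figure D1:**
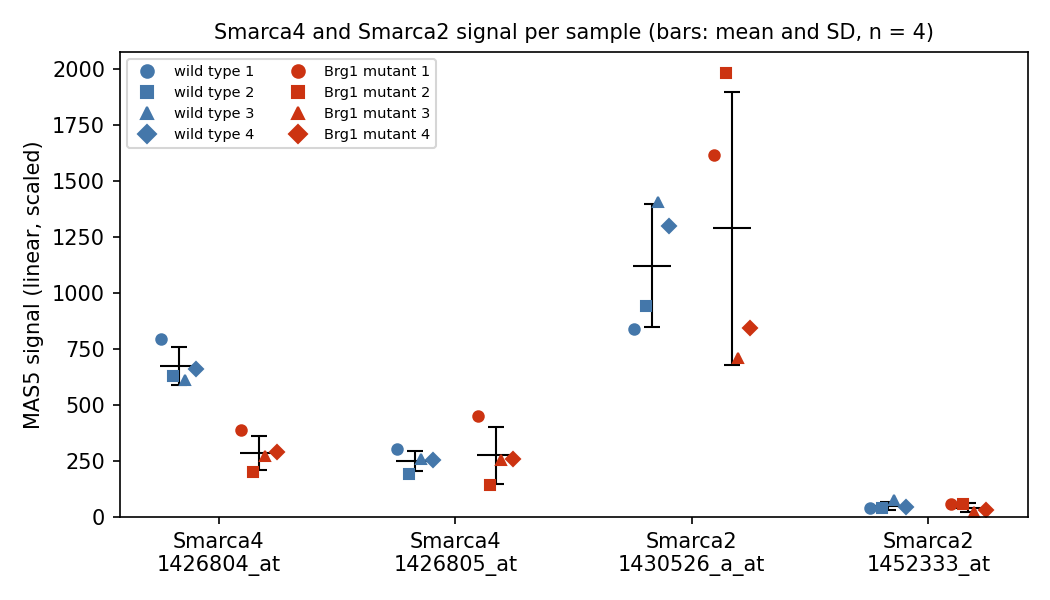
Linear MAS5 signal of each Smarca4 and Smarca2 probe set (y axis) in the 4 wild type and 4 Brg1 mutant samples, with black bars for the mean and SD. On the brighter Smarca4 probe set every mutant sample, at most 387.5, sits below every wild type sample, at least 612.1.

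Across the array, 671 probe sets were higher and 807 were lower in Brg1 mutant embryos, together 1478 or 6.56% of those tested. They stood for 840 of 11934 genes, 359 higher and 481 lower. At least a 2-fold change was estimated for 636 of the higher and 722 of the lower probe sets. The groups did not overlap for 1462 of the changed probe sets, and for 17.5% of all tested probe sets, where chance gives 2.86%. Of 142 changed probe sets that were a second reading of a changed gene, 6 went the opposite way. The split into higher and lower depended on the scaling: quantile normalization gave 496 higher and 809 lower, median centring 528 and 997, and centring on the 75th percentile 496 and 1104, while the median change of all tested probe sets moved from -0.05 to -0.14, -0.15 and -0.19 on the log2 scale. With no filter the majority turned, with 642 higher and 589 lower at a median change of 0.05. The number of calls moved widely when 1 sample was left out: it fell to 117, 442, 208 and 73 without wild type replicates 1, 2, 3 and 4 and to 283 and 378 without mutant replicates 3 and 4, and rose to 2709 and 2926 without mutant replicates 1 and 2.

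The 4 mutant arrays were not alike. Hsd3b1, a steroidogenic enzyme of granulosa and luteal cells, read at least 6889 in mutant replicates 3 and 4 and at most 50.5 in the other 6 samples. The intermediate filament gene Vim read at least 3107 against at most 31.1. Mutant replicates 3 and 4 correlated with each other at r = 0.969 across tested probe sets, with wild type arrays at 0.747 to 0.758, and with mutant replicates 1 and 2 at 0.738 to 0.774. Wild type arrays correlated with one another at 0.916 to 0.969, and genes are not independent replicates here. Mutant replicates 1 and 2 carried spike-in control signal 6.05 and 3.80 times the wild type mean, against 1.40 and 0.711 times in replicates 3 and 4. Left without mutant replicates 3 and 4, the comparison called 810 probe sets higher and 701 lower, among them 287 of the 671 and 422 of the 807 above. Left without mutant replicates 1 and 2 it called 4126 higher and 5232 lower, among them 665 of the 671 and all 807. All 1478 changes kept their direction in both of these fits. For the 1462 of them whose groups did not overlap, leaving samples out could not turn the direction. The same holds for every gene named below whose groups did not overlap. List calls without a pair, as under every other setting, used the preset correlation of 0.01 unless an estimated one is named: with an estimated correlation 0 of 25 lists passed in either fit, with a lowest adjusted p of 0.571 without replicates 3 and 4 and 0.0986 without replicates 1 and 2. In neither fit did camera call BAF and PBAF subunits, other remodellers, histone and DNA modifying enzymes, mRNA decay, pluripotency, histones, imprinted genes, or oviduct, sperm or blood markers (camera adjusted p between 0.0715 and 0.991). Of the 79 other genes named below that passed, 79 kept their direction whichever sample was left out, and 15 kept the call in all 8 such fits: Fxyd6, Bhlhe40, Rbms1, Dennd1b, Rras, 4930526I15Rik, Glis1, Dusp5, Insm1, Btn1a1, Taf9b, Ampd3, Dhx8, Zar1 and H1f8. The number called was 18, 40, 29 and 15 without wild type replicates 1 to 4, and 78, 79, 34 and 42 without mutant replicates 1 to 4. Of other tested probe sets of genes that passed, 16 passed in the same direction, 19 did not pass and had the same sign, and 7, of Smarca4, Polr1d, Eif4ebp1, Kdm5b and Wwtr1, did not pass and had the opposite sign. Besides the 6 of the 79 genes given below only as a lower limit, 29 had a log2 change over 1.5 times as large without mutant replicates 1 and 2 as without replicates 3 and 4: Ahnak, Skil, Hexa, Dusp5, Insm1, Taf9b, Stat4, Cacnb2, Egfl6, Fcgbp, Smarcd2, Kmt2e, Kdm5b, Eif4ebp1, Taf5, Obox3, Exosc9, Prc1, Cdc6, Sesn2, Casp6, Hsp90b1, Trib3, Hspa8, Tbx3, Krt18, Ndufa1, Ndufb8 and Hk1. For Gadd45g alone of the 73 it was the other way round. Of 45 named genes that did not pass, again without lower limits, the log2 change was over 1.5 times as large without replicates 1 and 2 for 23, over 1.5 times as large without replicates 3 and 4 for 4, and of opposite sign in these fits for 9.

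The 12 largest falls among genes that separated all mutant from all wild type samples were as follows. Glis1, a Krüppel-like zinc finger factor of the oocyte and early embryo, fell by 4.34 on the log2 scale (SE 0.393, limma adjusted p = 0.00153), 20.3-fold, from a log2 signal of 8.31 ± 0.70 to 3.97 ± 0.43 (SD, n = 4 each). The zinc finger factor gene Insm1 fell 12-fold (log2 change -3.58, limma adjusted p = 0.00771) and its second probe set fell too (log2 change -2.68, limma adjusted p = 0.00736). Taf9b, which encodes a TFIID and SAGA subunit, fell 10.2-fold, and Dusp5, a phosphatase of ERK kinases, fell 13.7-fold. Btn1a1, Rrp9, Stat4, Cacnb2, Ampd3, Egfl6, Fcgbp and Cst7 made up the rest of the 12, with falls between 6.42-fold and 11.6-fold. Mutant signal lay under the background bound on 3 of 4 arrays for Glis1 and Dusp5, on 2 for Stat4 and Egfl6 and on 1 for Btn1a1, Rrp9, Cacnb2 and Cst7. Leaving out mutant replicates 3 and 4, only Stat4 of the 12 lost its call (log2 change -1.55 against -3.08 over all samples, limma adjusted p = 0.0675), and without replicates 1 and 2 none did.

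Among the 12 largest rises, 6 genes lay under the background bound on every wild type array and so have only a lower limit. Tceal9 was at least 28.4-fold higher (limma adjusted p = 0.0118), Bex3 at least 19.2-fold and Fxyd6, a regulator of the sodium pump, at least 11-fold. Bhlhe40, a basic helix-loop-helix repressor, was at least 7.41-fold higher (limma adjusted p = 0.00211), the small GTPase gene Rras at least 7.23-fold and the lysosomal membrane gene Scarb2 at least 7.19-fold. Skil, which encodes the SMAD corepressor SnoN, rose 14.4-fold, and Hexa, a lysosomal hexosaminidase subunit, 11.6-fold. Ahnak, Rbms1 and 4930526I15Rik lay under the bound on 3 of 4 wild type arrays, Dennd1b on 2 and Hexa on 1. Other tested probe sets of Ahnak, Dennd1b and Skil did not pass (limma adjusted p = 0.688, 0.328 and 0.277), whereas that of Scarb2 did (limma adjusted p = 0.0441). Mutant replicates 1 and 2 alone give lower limits of 4.48-fold for Tceal9, 5.58-fold for Bex3, 20.9-fold for Fxyd6, 4.78-fold for Bhlhe40, 4.13-fold for Rras and 3.005-fold for Scarb2. Replicates 3 and 4 alone give 180-fold, 66.4-fold, 5.76-fold, 11.48-fold, 12.7-fold and 17.2-fold. Without replicates 3 and 4 the rise of Skil was 1.95 on the log2 scale (limma adjusted p = 0.0203) against 5.75 without replicates 1 and 2. Ahnak, Scarb2 and Hexa lost their calls without replicates 3 and 4 (limma adjusted p = 0.0836, 0.0601 and 0.0700). Log2 changes were then 3.14 for Ahnak and 2.20 for Hexa against 4.59 and 3.54 over all samples.

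**Figure D2:**
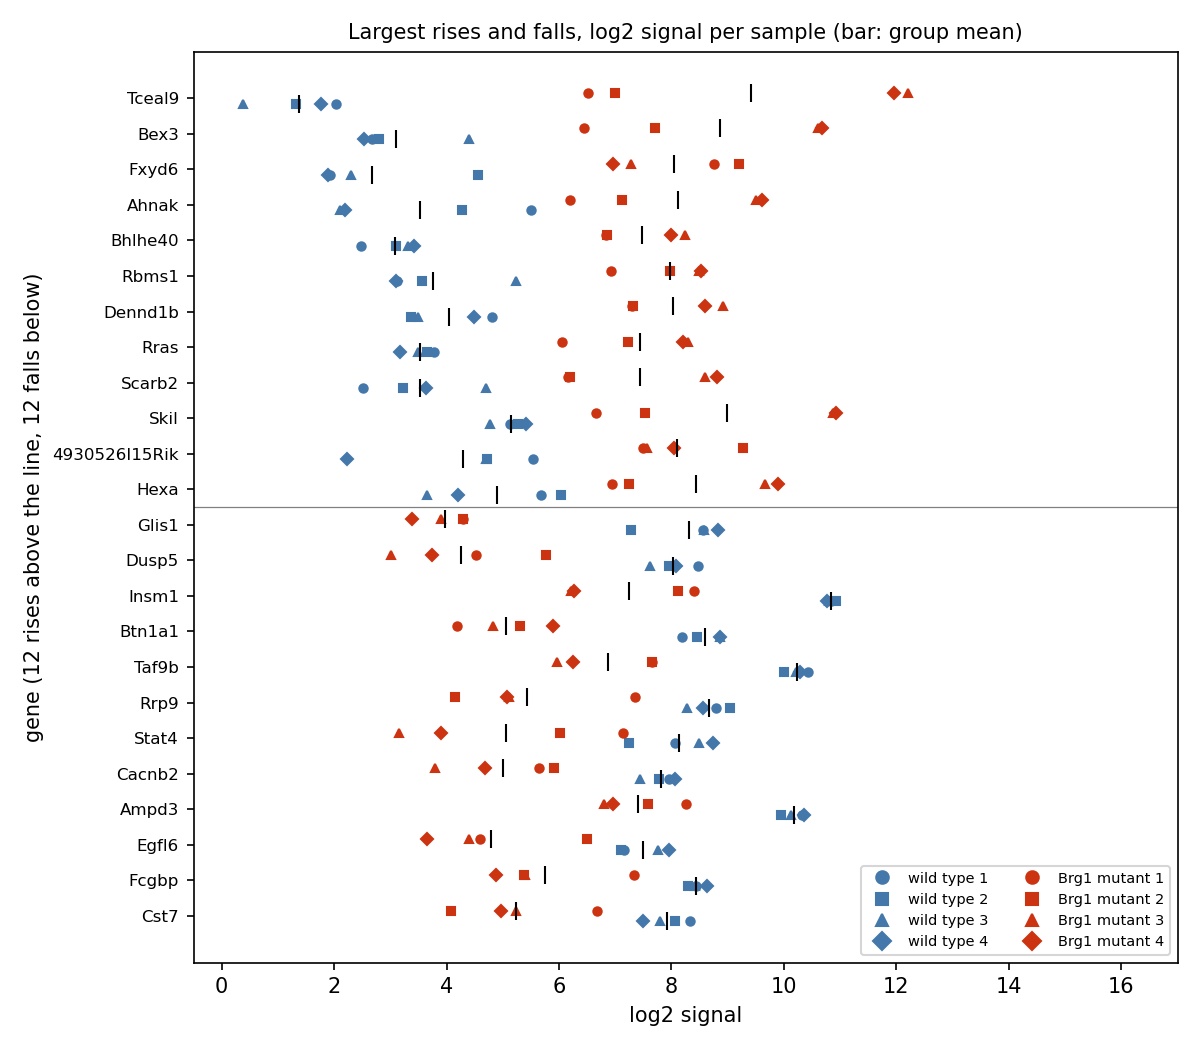
Log2 signal (x axis) of the 12 genes with the largest rise and the 12 with the largest fall (y axis), with 1 symbol per sample and a black bar for each group mean. Every mutant sample lies beyond every wild type sample for each of the 24 genes, and for Tceal9 mutant replicates 3 and 4 lie above replicates 1 and 2.

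The lists of cell division genes had lower medians in the mutants, but chance was not excluded for them. Of 35 splits of the samples into 4 and 4, 3 gave a camera p as small for mitosis, and 3 for DNA replication. On the same arrays the ratio of 3 prime to 5 prime signal was lower in all 4 mutant than in all 4 wild type samples, at most 15.048 against at least 16.303 for actin and at most 7.33 against at least 8.58 for Gapdh (exact permutation p = 0.0286 and adjusted p = 0.214 for each). Of 84 tested mitosis genes, 15 fell, 0 rose and 69 did not pass, and 19 fell when adjusted over the list alone (camera adjusted p = 1.4e-06, but adjusted p = 0.426 with an estimated correlation). Among them Cenpa, the centromeric histone H3 variant, fell 3.38-fold (limma adjusted p = 0.0145), Prc1, a spindle midzone organiser, 2.96-fold, Racgap1, a cytokinesis regulator, 2.71-fold, and the kinesin gene Kif18a 2.52-fold. Of 62 DNA replication genes, 8 fell, 0 rose and 54 did not pass, and 14 fell when adjusted over the list alone (camera adjusted p = 0.000205, but adjusted p = 0.426 with an estimated correlation). The loading factor gene Cdc6 fell 3.14-fold, the primase gene Prim1 2.85-fold, the helicase subunit gene Mcm5 2.67-fold and the GINS subunit gene Gins2 2.49-fold (limma adjusted p between 0.0118 and 0.0167). The median change was -0.41 for the mitosis list and -0.36 for DNA replication on the log2 scale. Without mutant replicates 3 and 4, which carry the granulosa marker signal, the medians were -0.34 and -0.25 (camera adjusted p = 0.00132 and 0.00511, but adjusted p = 0.571 for each with an estimated correlation). Without replicates 1 and 2 they were -0.65 and -0.66 (camera adjusted p = 3.69e-06 and 0.00106, but adjusted p = 0.249 for each with an estimated correlation).

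Genes of the RNA polymerase II machinery were lower as well, with 8 of 82 falling, 0 rising and 74 not passing (camera adjusted p = 0.000192, but adjusted p = 0.402 with an estimated correlation). Adjusted over the list alone, 11 fell, on the arrays whose 3 prime to 5 prime ratios moved with the groups as given above. Besides Taf9b, the polymerase subunit gene Polr2d fell 2.09-fold (limma adjusted p = 0.0297), the Mediator gene Med29 2.12-fold (limma adjusted p = 0.0298) and the TFIID gene Taf5 2.08-fold (limma adjusted p = 0.0310). With mutant replicates 3 and 4 left out Taf9b still passed, and Polr2d, Med29 and Taf5 did not (limma adjusted p = 0.0662, 0.0713 and 0.0628). Their log2 changes were then -0.93, -0.90 and -0.76 against -1.06, -1.09 and -1.06 over all samples. Of the other tested probe sets of Med29, 1 passed and 1 did not (limma adjusted p = 0.0278 and 0.821). Of 82 ribosome biogenesis genes, Rrp9, a U3 snoRNP component, fell 9.48-fold and Polr1d, shared by RNA polymerases I and III, 2.03-fold. The other 80 did not pass and 0 rose, and 1 fell when adjusted over the list alone (camera adjusted p = 0.00259, but adjusted p = 0.644 with an estimated correlation). Other tested probe sets of Polr1d did not pass (limma adjusted p = 0.678, 0.824 and 0.869), and its own call was lost without mutant replicates 3 and 4 (limma adjusted p = 0.0788), at a log2 change of -0.98 against -1.02. Dkc1 and Bop1 had log2 changes of -0.84 and -0.82 and did not pass (limma adjusted p = 0.0505 and 0.0515). Dkc1 passed on 1 of 2 other probe sets (log2 change -1.15, limma adjusted p = 0.0307; the other 0.196) and without mutant replicates 3 and 4 (limma adjusted p = 0.0463). For the RNA polymerase II and ribosome biogenesis lists the camera adjusted p without mutant replicates 3 and 4 was 0.00132 and 0.000113, and without replicates 1 and 2, with their high spike-in signal, it was 0.00187 and 0.182, so that the ribosome biogenesis call ended while the median stood at -0.32 against -0.34 over all samples. With an estimated correlation the adjusted p was 0.571 and 0.685 without replicates 3 and 4 and 0.0986 and 0.721 without replicates 1 and 2. That call was also lost without mutant replicate 2 alone and with array weights (camera adjusted p = 0.244 and 0.236).

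**Figure D3:**
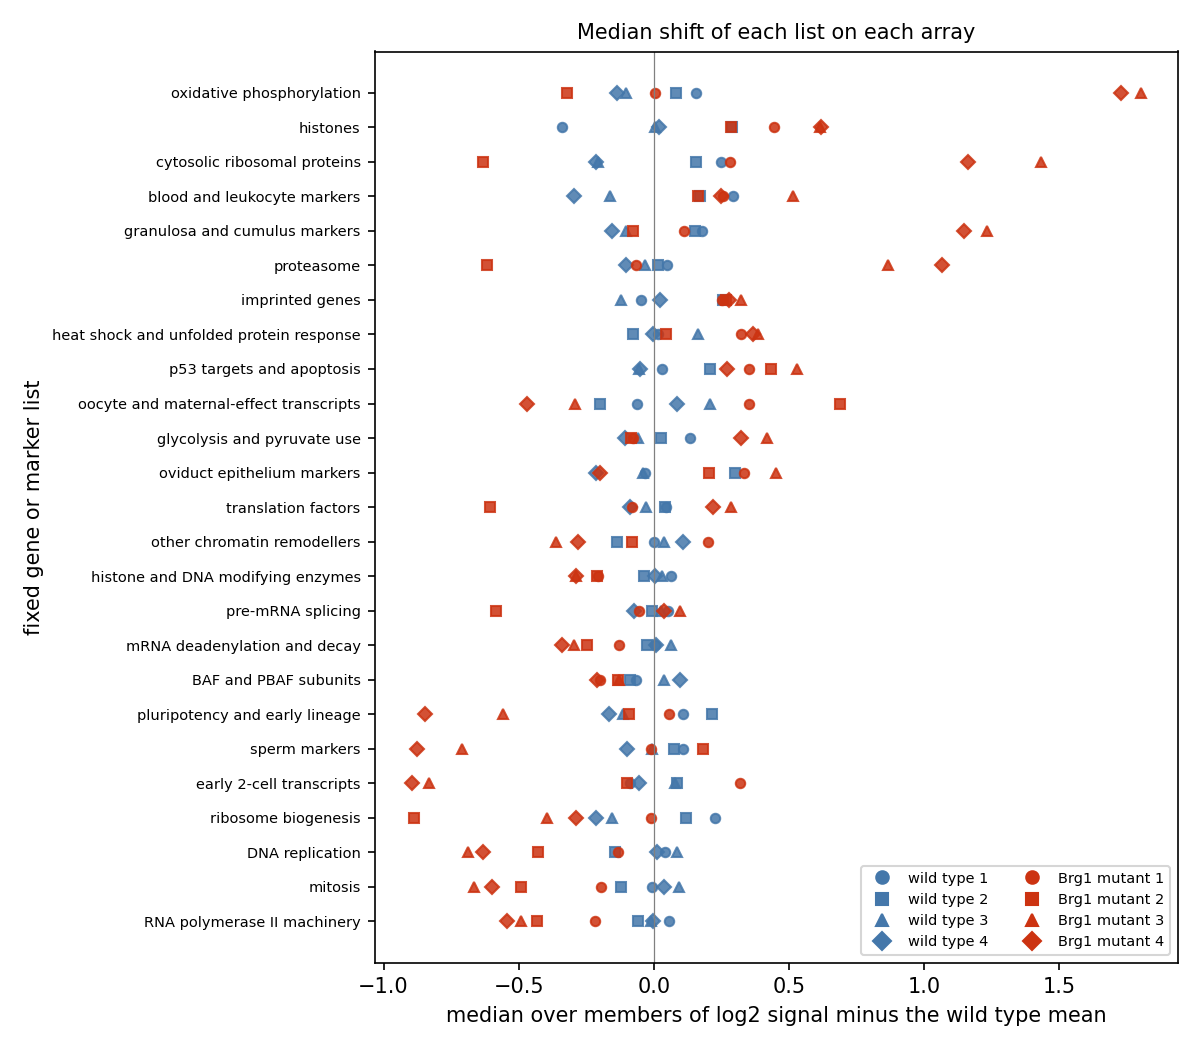
Median over the members of each fixed list (y axis) of the log2 signal minus the wild type mean (x axis), with 1 symbol per sample. The mitosis and RNA polymerase II lists lie below 0 in all 4 mutant samples, whereas oxidative phosphorylation is high in mutant replicates 3 and 4, at 1.80 and 1.73, and at 0.00 and -0.32 in replicates 1 and 2.

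The oxidative phosphorylation list was higher in the mutants (camera adjusted p = 1.27e-06, but adjusted p = 0.574 with an estimated correlation), with 3 of 72 genes rising, 0 falling and 69 not passing; 3 rose when adjusted over the list alone. The complex I subunit genes Ndufv3, Ndufa1 and Ndufb8 rose 2.89-fold, 2.65-fold and 2.56-fold (limma adjusted p = 0.0167, 0.0327 and 0.0379), and without mutant replicates 3 and 4 only Ndufv3 of these passed (limma adjusted p = 0.0212, 0.0705 and 0.0947). Log2 changes were then 0.87 for Ndufa1 and 0.79 for Ndufb8 against 1.41 and 1.36 over all samples. Cox15 had a log2 change of 1.59 and did not pass (limma adjusted p = 0.0530). Cytosolic ribosomal protein genes were higher as a list (median 0.55, camera adjusted p = 0.000381, but adjusted p = 0.638 with an estimated correlation), although 0 of 42 members passed, also when adjusted over the list alone: Rpl11, Rpl12 and Rpl13a had log2 changes of 0.91, 0.86 and 0.87, and Rps25 of -0.76. Granulosa marker signal moved with both lists, whose medians were 1.78 and 1.28 without mutant replicates 1 and 2, and -0.17 and -0.09 without replicates 3 and 4, where neither was called (camera adjusted p = 0.269 and 0.301). Of 42 genes of the p53 and apoptosis list, 5 rose, 1 fell and 36 did not pass, and 10 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0159, but adjusted p = 0.402 with an estimated correlation). The executioner caspase gene Casp6 and the inhibitor of apoptosis gene Birc2 rose 2.30-fold and 2.31-fold, Gadd45g rose 6.93-fold from a signal under the background bound on 2 wild type arrays, and Sesn2, a stress-induced regulator of TORC1, fell 3.77-fold. Casp6 and Birc2 did not pass without mutant replicates 3 and 4 (limma adjusted p = 0.0797 and 0.0970), at log2 changes of 0.92 and 0.99 against 1.20 and 1.21. The call of the list was lost without mutant replicates 1 and 2 (camera adjusted p = 0.105), where the median was 0.40 against 0.15 over all samples. It was also lost with array weights and with the mean of a gene's probe sets (camera adjusted p = 0.0574 and 0.0540). The 3 prime to 5 prime ratios given above moved with the groups on the same arrays, and their part in the change of this list was not tested.

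Oocyte transcripts moved both ways. Of 74 tested oocyte and maternal-effect genes, 8 rose, 3 fell and 63 did not pass, and 9 rose and 4 fell when adjusted over the list alone. The list was not called (camera adjusted p = 0.215). Zar1, a maternal-effect gene needed at the oocyte-to-embryo transition, rose 6.77-fold (log2 change 2.76, SE 0.207, limma adjusted p = 0.000674). H1f8, the oocyte linker histone, rose 5.77-fold (limma adjusted p = 0.00771) and Plat, tissue plasminogen activator, 2.12-fold (limma adjusted p = 0.0237), while the homeobox gene Obox3 fell 3.18-fold (limma adjusted p = 0.0206). All 4 passed with either mutant pair left out. Of the maternal-effect and zona genes fixed in advance, Nlrp5, Dppa3 and Zp3 did not pass (log2 changes 1.04, 0.21 and -0.01; limma adjusted p = 0.0759, 0.730 and 0.990), although Dppa3 passed without mutant replicates 3 and 4 (log2 change 0.72, limma adjusted p = 0.0370). The list was called higher without mutant replicates 3 and 4, with 21 rising, 2 falling and a median of 0.59 (camera adjusted p = 7.86e-06, but adjusted p = 0.571 with an estimated correlation). After quantile normalization of the same samples, 8 rose, 4 fell and the median was 0.19. Without replicates 1 and 2, with 9 rising and 26 falling, it was not called and had a median of -0.34 (camera adjusted p = 0.0910). Leaving out mutant replicate 3 or 4 alone was enough for the call (camera adjusted p = 0.0436 and 0.0201).

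Transcripts typical of the 2-cell stage were not called as a group over all samples (camera adjusted p = 0.0618): of 29 tested, Pramel6 fell 2.59-fold (limma adjusted p = 0.0399), Zfp809, a zinc finger repressor of retroelements, rose 2.66-fold (limma adjusted p = 0.0329) and 27 did not pass, with the same 1 fall and 1 rise when adjusted over the list alone. Neither Pramel6 nor Zfp809 passed without mutant replicates 3 and 4 (limma adjusted p = 0.106 and 0.0919), at log2 changes of -1.12 and 1.15 against -1.37 and 1.41. Eif1ax, Hspa1b and Ubtfl1 had log2 changes of -0.84, -0.18 and -1.27 and did not pass (limma adjusted p = 0.0906, 0.784 and 0.0657). With mutant replicates 3 and 4 left out Eif1ax fell by 1.28 on the log2 scale (limma adjusted p = 0.0123), while its other tested probe set read 1.56 higher over all samples (limma adjusted p = 0.0524). Zscan4c and Zscan4d had no probe set assigned to that gene alone and were not analysed here. This list was called lower without mutant replicates 1 and 2 (median -0.90, camera adjusted p = 0.000696, but adjusted p = 0.0986 with an estimated correlation, and 0.644 over all samples) and was not called without replicates 3 and 4 (median 0.10, camera adjusted p = 0.897). It was also called lower without wild type replicate 1 or mutant replicate 1 alone (camera adjusted p = 0.0443 and 0.00227). The same held with array weights, with no filter and without _x_at and _s_at probe sets (camera adjusted p = 0.000927, 0.0206 and 0.0288). Of 47 pluripotency and early lineage genes, 3 fell, 1 rose and 43 did not pass, with 4 falling and 5 rising when adjusted over the list alone (camera adjusted p = 0.291). The falls were Tbx3, 3.81-fold, the Krüppel-like factor gene Klf5, 3.52-fold, and Wwtr1, which encodes the Hippo pathway coactivator TAZ, 3.02-fold (limma adjusted p between 0.0157 and 0.0209), and each passed with either mutant pair left out. The keratin gene Krt18 rose 5.02-fold, and did not pass without mutant replicates 3 and 4 (log2 change 1.45 against 2.33, limma adjusted p = 0.0562). A second tested probe set of Klf5 did not pass (limma adjusted p = 0.878), nor did Pou5f1, the gene of OCT4 (log2 change -0.17, limma adjusted p = 0.821).

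Chromatin genes showed single changes and no list called by camera over all samples. Fry, which compares a list with no other genes, passed BAF and PBAF subunits (fry adjusted p = 0.00359) and histone and DNA modifying enzymes (fry adjusted p = 0.0135). Of 21 BAF and PBAF subunit genes, Smarca4 and Smarcd2, which encodes BAF60B and fell 1.92-fold (limma adjusted p = 0.0369), were the 2 that passed, also when adjusted over the list alone (camera adjusted p = 0.228). Phf10 and Arid1a had log2 changes of -0.69 and -0.91 (limma adjusted p = 0.0988 and 0.154). Of 29 other remodeller genes, the NuRD subunit gene Mta2 fell 2.89-fold (limma adjusted p = 0.0181) and 28 did not pass; 1 fell when adjusted over the list alone (camera adjusted p = 0.252). Hells, Chd6 and Baz1b had log2 changes of -0.85, -0.75 and -0.66 (limma adjusted p = 0.0703, 0.0959 and 0.0961). Of 59 histone and DNA modifying enzymes, 4 fell, 1 rose and 54 did not pass, with 5 falling and 1 rising when adjusted over the list alone (camera adjusted p = 0.178). Setdb2, the H3K4 demethylase gene Kdm5b and the acetyltransferase gene Kat7 fell 2.57-fold, 2.47-fold and 1.85-fold (limma adjusted p = 0.0174, 0.0254 and 0.0358), and Kmt2e rose 4.53-fold (limma adjusted p = 0.0209). The other tested probe sets of Kdm5b did not pass (limma adjusted p = 0.979 and 0.996). Of 11 histone genes, H1f8 rose, Cenpa fell and 9 did not pass, with 3 rising and 2 falling when adjusted over the list alone (camera adjusted p = 0.215, and 0.0264 with no filter). H2az2 and H1f2 had log2 changes of -0.89 and 4.03 (limma adjusted p = 0.0626 and 0.0670). That of H1f2, under the background bound on 2 wild type arrays, was 1.44 without mutant replicates 3 and 4 and 6.63 without replicates 1 and 2.

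Genes of RNA processing and translation moved both ways, with no list called by camera over all samples. In pre-mRNA splicing, 6 of 86 fell, 1 rose and 79 did not pass, with 10 falling and 4 rising when adjusted over the list alone (camera adjusted p = 0.291). The helicase gene Dhx8 fell 2.82-fold (limma adjusted p = 0.00976), and Hnrnpd, Rbm17 and Lsm2 fell 2.32-fold, 2.16-fold and 2.10-fold, Lsm2 not without mutant replicates 3 and 4 (log2 change -0.87 against -1.07, limma adjusted p = 0.0788). In mRNA deadenylation and decay, 5 of 58 fell, 3 rose and 50 did not pass, with 7 falling and 4 rising when adjusted over the list alone (camera adjusted p = 0.243, fry adjusted p = 0.00319). The exonuclease gene Dis3l fell 3.13-fold, the decapping-associated gene Lsm1 2.67-fold and the exosome gene Exosc10 2.09-fold, while Exosc9 rose 3.27-fold (limma adjusted p between 0.0118 and 0.0368), the latter pair of exosome genes not without mutant replicates 3 and 4 (log2 changes -1.10 and 1.20 against -1.06 and 1.71, limma adjusted p = 0.0601 and 0.0680). Among 45 translation factors, the eIF2B subunit genes Eif2b4 and Eif2b1 fell 2.73-fold and 1.73-fold, Eif4ebp1, an inhibitor of cap-dependent initiation, rose 4.77-fold, and 42 did not pass; 3 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.849, with a median of -0.06 and a mean of 0.05). Eif2b1 did not pass without mutant replicates 3 and 4 (log2 change -0.81 against -0.79, limma adjusted p = 0.0505). The rise of Eif4ebp1 was 0.99 on the log2 scale without replicates 3 and 4 (limma adjusted p = 0.0435) and 3.52 without replicates 1 and 2. Of its 2 other tested probe sets 1 passed in the same direction and 1 did not pass (limma adjusted p = 0.0313 and 0.933). Etf1 had a log2 change of -0.92 (limma adjusted p = 0.0548), with 1 of 4 other probe sets passing (log2 change -1.22, limma adjusted p = 0.0332; the others 0.0711, 0.131 and 0.345). Of 41 proteasome genes, 0 passed, also when adjusted over the list alone (camera adjusted p = 0.148), with log2 changes of 1.86, -0.66, 0.90 and 1.38 for Psma7, Psmf1, Psmd2 and Psmb7. The list was called higher without mutant replicate 1 or 2 alone and with array weights (camera adjusted p = 0.0499, 0.000589 and 4.65e-05). The proteasome list was called higher without mutant replicates 1 and 2 (camera adjusted p = 3.69e-06) and lower without replicates 3 and 4 (camera adjusted p = 0.0162), the translation factor list likewise (camera adjusted p = 0.0349 and 0.00427), and the splicing list was called lower without replicates 3 and 4 (camera adjusted p = 0.00226). With an estimated correlation none of these passed: the adjusted p was 0.571 for all 3 lists without replicates 3 and 4, and 0.0986 for the proteasome and 0.25 for translation factors without replicates 1 and 2. The falls without replicates 3 and 4 lay on mutant replicate 2. Its proteasome, translation factor and splicing medians were -0.62, -0.61 and -0.58 relative to the wild type mean. Those of mutant replicate 1, -0.07, -0.08 and -0.06, lay within the range of the wild type arrays.

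Stress, metabolic and imprinted genes were not called as lists by camera over all samples either. Of 51 heat shock and unfolded protein response genes, 5 rose, 1 fell and 45 did not pass, with 10 rising and 2 falling when adjusted over the list alone (camera adjusted p = 0.0618). The endoplasmic reticulum chaperone gene Hsp90b1 rose 2.69-fold, the constitutive chaperone gene Hspa8 2.38-fold and the stress-induced factor gene Atf3 4.33-fold, from a signal under the background bound on 1 wild type array, while Trib3 fell 2.88-fold (limma adjusted p between 0.0185 and 0.0232); all 4 passed with either mutant pair left out. Of 30 genes of glycolysis and pyruvate use, the hexokinase gene Hk1 rose 4.65-fold, the enolase gene Eno3 3.21-fold, the mitochondrial pyruvate carrier gene Mpc1 fell 2.40-fold and 27 did not pass, with the same counts of 2 and 1 when adjusted over the list alone (camera adjusted p = 0.291). Signals of Hk1 and Eno3 were under the background bound on 1 and 2 wild type arrays, and neither gene passed without mutant replicates 3 and 4 (log2 changes 1.66 and 1.38 against 2.22 and 1.69, limma adjusted p = 0.157 and 0.134). Pdk1 had a log2 change of 1.05 (limma adjusted p = 0.0975). Of 26 imprinted genes, Plagl1 rose 2.10-fold (limma adjusted p = 0.0254) and 25 did not pass, with 1 rising when adjusted over the list alone (camera adjusted p = 0.0618). Plagl1 did not pass without mutant replicates 3 and 4 (log2 change 0.96 against 1.07, limma adjusted p = 0.0583), and Peg3, Kcnq1ot1 and Ndn had log2 changes of 1.26, 1.58 and 1.38 (limma adjusted p = 0.0576, 0.0683 and 0.0875). Signal of Kcnq1ot1 lay under the background bound on 3 wild type arrays and 1 mutant array. Peg3 passed without mutant replicates 3 and 4 (limma adjusted p = 0.0438), and of the 3 other tested probe sets of Ndn 1 passed and 2 did not (limma adjusted p = 0.0343, 0.321 and 0.709). The imprinted list was called without mutant replicate 1 and with centring on the 75th percentile (camera adjusted p = 0.0499 and 0.0490), and it passed fry (fry adjusted p = 0.0174). The stress list was called without wild type replicates 3 and 4 and mutant replicate 2, each left out alone (camera adjusted p = 0.0272, 0.0481 and 0.00661). It was also called with quantile normalization, with no filter and without _x_at and _s_at probe sets (camera adjusted p = 0.0155, 0.0428 and 0.0461). Without mutant replicates 1 and 2 the stress list and the glycolysis list were called higher (camera adjusted p = 0.0205 and 0.0237, but adjusted p = 0.307 and 0.249 with an estimated correlation), the glycolysis list also with array weights (camera adjusted p = 0.0475).

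Marker genes of other cell types that can accompany embryos were tested in the same way. Granulosa and cumulus markers were called higher as a list (camera adjusted p = 0.0396, but adjusted p = 0.574 with an estimated correlation), with 0 of 18 passing singly, also when adjusted over the list alone. Hsd3b1, Fst and Inha had log2 changes of 5.38, 4.04 and 2.54, with Hsd3b1 under the background bound on 3 wild type arrays and Fst on 1. Vim, under the bound on all 4, read at least 12.9-fold higher, a limit carried by mutant replicates 3 and 4: Vim read 31.1 in replicate 1 and lay under the bound in replicate 2. Without mutant replicates 3 and 4 the log2 changes of Hsd3b1, Fst and Inha were 1.41, 2.08 and 0.19. Hsd3b1, Vim, Fst and Inha did not pass (limma adjusted p between 0.0512 and 0.164). A second probe set of Fst passed (limma adjusted p = 0.0495). Without mutant replicates 3 and 4 the list was not called (camera adjusted p = 0.897), and it was also not called without either of them alone (camera adjusted p = 0.116 and 0.121) or without wild type replicates 3 or 4 (camera adjusted p = 0.0569 and 0.0535). The call was also lost with quantile normalization and with the upper 30% filter (camera adjusted p = 0.0576 and 0.108). Of 7 blood and leukocyte markers, Lyz1 rose (log2 change 5.32, limma adjusted p = 0.0224) from a signal under the background bound on 3 of 4 wild type arrays, 6 did not pass, and 1 rose when adjusted over the list alone (camera adjusted p = 0.0618, fry adjusted p = 0.0347). Lyz1 did not pass without mutant replicates 3 and 4 (log2 change 4.47, limma adjusted p = 0.0866), and Lyz2, Laptm5 and Cd52 had log2 changes of 0.51, 0.50 and 1.67. The blood list was called without wild type replicate 1 (camera adjusted p = 0.0316). Of 6 oviduct epithelium and 8 sperm markers, 0 passed, also when adjusted over the list alone (camera adjusted p = 0.291 and 0.243). Ovgp1, Cldn3 and Upk1a of the oviduct had log2 changes of 0.91, 0.23 and -0.10, and Ldhc, Prm2, Odf2 and Acr of sperm of -1.28, -0.98, -0.76 and -0.39. Clu, counted here as an oviduct marker, read at least 6032 in mutant replicates 3 and 4 and at most 178.8 in the others (limma adjusted p = 0.182 over all samples).

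**Figure D4:**
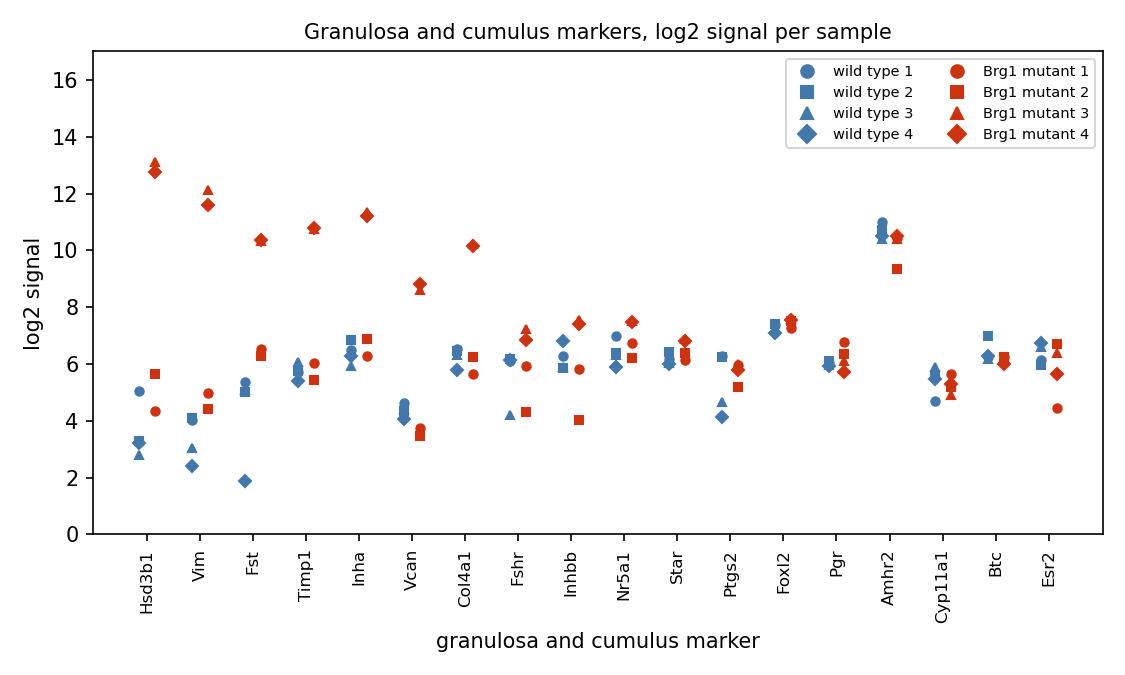
Log2 signal (y axis) of the 18 tested granulosa and cumulus markers (x axis), with 1 symbol per sample. Hsd3b1 lies at 13.11 and 12.75 in mutant replicates 3 and 4 and at most at 5.66 elsewhere, while Cyp11a1 and Amhr2 are not raised in these 2 samples.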

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

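The tests of somatic RNA, labelled RNA amount and the mutation on mutant replicates 3 and 4, the 3 tests of dilution, and the list of control signals were chosen only after the result was seen, and the 2 tests of oocyte transcripts, the splits counted by list, and the estimated correlations and matched lists in fits without replicates 3 and 4 were added after the fits or counts they rest on had been seen. The rule for the verdict on labelled RNA amount was changed, and the test of the mutation was replaced 2 times, after their values had been seen.

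Mutant replicates 3 and 4 stood apart from the 6 other arrays. Of 26 fixed granulosa and cumulus markers on the array, 18 passed the filter, which used the mean over all 8 arrays. Mean log2 signals of Vim, Hsd3b1 and Vcan were 3.39, 3.58 and 4.36 in wild type and 4.69, 4.99 and 3.61 in mutant replicates 1 and 2. They passed the limit of 5.25 only through replicates 3 and 4. So did Fst, which averaged 4.33 in wild type and 6.41 in mutant replicates 1 and 2, and under the limit over these 6 arrays. The count below therefore rests in part on the choice of filter. The matched random lists passed the same filter. Of the 18 tested granulosa and cumulus markers, 12 lay above all 6 other arrays on both (matched random lists have a median of 4, and 8 bounds their central 95%; permutation p = 1e-04, the smallest these draws can give, adjusted p = 4e-04), with Hsd3b1 at least 6889, Vim at least 3107 and Inha at least 2364, and 2 of the 18 above the median signal in wild type embryos. The gap to every other array was only 0.04 to 0.68 log2 units for Foxl2, Star, Nr5a1, Inhbb and Fshr. It was over 1 log2 unit for 7 of the 12 markers. RNA of cells that carry these markers is therefore a candidate source, as a hypothesis; Cyp11a1, Amhr2, Ptgs2, Pgr, Btc and Esr2 were not raised, and 2 of 6 oviduct, 0 of 8 sperm and 3 of 7 blood markers met the same condition (adjusted p = 0.513, 1 and 0.328). Mutant replicates 3 and 4 correlated with mutant replicates 1 and 2 at no more than 0.774 across tested probe sets. Correlations were at least 0.916 among wild type arrays, 0.895 between mutant replicates 1 and 2 and 0.969 between 3 and 4. An effect of the Brg1 mutation alike in all 4 mutants could not set 2 of them apart. The correlations chosen to test it restate the pattern, so they decide nothing. An effect of the mutation that varies between samples stays open. For less labelled embryo RNA, the mean log2 spike-in signal of replicates 3 and 4 was -0.389 relative to the highest wild type array, but replicate 3 lay above that array and replicate 4 below it. Spike-in signal was 1.40 and 0.711 times the wild type mean in replicates 3 and 4, and 6.05 and 3.80 times in replicates 1 and 2. Yet replicates 1 and 2 correlated with wild type arrays at 0.828 to 0.89, and replicates 3 and 4 at 0.747 to 0.758. This argues against less labelled RNA as the whole cause, and a part stays open.

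Oocyte and maternal-effect transcripts were higher on mutant replicates 1 and 2. Their median without replicates 3 and 4, 0.59, lay at percentile 100 of random lists matched on signal (central 95% from -0.14 to 0.25), higher than for genes of like brightness. After quantile normalization without replicates 3 and 4 the median fell to 0.19, with 8 higher and 4 lower instead of 21 and 2, and the list was still called (camera adjusted p = 0.0169; between 7.86e-06 and 0.903 over the other alternatives of this list), but not with an estimated correlation (adjusted p = 0.788). In that fit 0.19 lay at percentile 99.7 of matched random lists (central 95% from -0.212 to 0.135). Random lists were drawn gene by gene and ignore the correlation within the oocyte list, estimated at 0.297 before and 0.264 after quantile normalization. Genes that vary together can reach such percentiles through differences between single arrays. The percentiles therefore exclude neither a shift that depends on brightness nor the scaling, and both stay open. The high spike-in signal of these samples and the mutation remain open and cannot be separated with 2 samples.

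The mitosis, DNA replication and RNA polymerase II lists were lower, also without mutant replicates 3 and 4 (camera adjusted p = 0.00132, 0.00511 and 0.00132, but adjusted p = 0.571 for each with an estimated correlation). Their medians there lay at percentiles 0.03, 0.88 and 0.02 of matched random lists. Relative to the wild type mean, mitosis medians on mutant replicates 1 and 2 were -0.19 and -0.49, and RNA polymerase II medians -0.22 and -0.43. All 4 lay below every wild type array. DNA replication medians were -0.13 and -0.43, against -0.15 in wild type replicate 2. As these calls rest on 2 mutant arrays and were lost with an estimated correlation, dilution by the RNA that marks replicates 3 and 4 is not excluded as the whole cause. Over all alternatives the adjusted p ran from 7.65e-09 to 0.426 for mitosis, 1.69e-05 to 0.426 for DNA replication and 3.6e-06 to 0.402 for RNA polymerase II, the highest with an estimated correlation. Their medians over all samples lay at percentiles 0.03, 0.48 and 0.01 of matched random lists, lower than for genes of like brightness. Such lists ignore the correlation within a list, estimated over all samples at 0.194, 0.147 and 0.0398. The percentiles therefore cannot exclude a shift that depends on brightness. Over the 35 splits of the 8 samples into 4 and 4, chance cannot be excluded for mitosis (3 splits with a camera p as small; real 1.12e-07, smallest other 2.84e-10) or DNA replication (3 splits; 3.29e-05, smallest other 1.83e-07), and for RNA polymerase II (1 split, the real one; 2.3e-05, smallest other 3.77e-05) only at the smallest share the splits can give, without adjustment over the 8 lists. An effect of the mutation stays open for all 3 lists, as does a difference in RNA quality or labelling, since the ratios of 3 prime to 5 prime signal given below were lower on all 4 mutant arrays; this was not tested.

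For the number of changed probe sets, 1 of the 35 splits, the real one, gave as many (1478, highest other 6). Chance is excluded only at this share, the smallest the splits can give. Every other split mixed mutant and wild type samples, which widens the spread within its groups. For the number of lists called chance cannot be excluded: 18 splits gave as many as the real 8, the highest other giving 13. By list, a camera p as small came from 1 split for p53 targets and apoptosis (0.00446, smallest other 0.0116), again the smallest share and unadjusted, with an adjusted p of 0.402 with an estimated correlation. It came from 15 for oxidative phosphorylation (5.09e-08, smallest other 1.63e-22), 15 for granulosa and cumulus markers (0.0127, smallest other 2.67e-05), 17 for cytosolic ribosomal proteins (7.63e-05, smallest other 1.62e-21) and 20 for ribosome biogenesis (0.000622, smallest other 6.21e-16). Splits that put mutant replicates 3 and 4 on one side follow the structure of the samples.

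A search for 1 sample far from the others in its group cannot flag a split into 2 and 2, as between the mutant pairs. In 10 of 334 groups of 4 samples 1 sample lay far from the others, where chance gives about 1 in 20, or 16.7. On the log2 scale these were Bex3 at 4.41 in wild type replicate 3, Fxyd6 at 4.57 in wild type replicate 2, Hells at 9.07 in mutant replicate 1, Zfp809 at 5.23 in wild type replicate 1, Etf1 at 10.80 in wild type replicate 2, Birc2 at 6.17 in wild type replicate 3, Ndufa1 at 8.92 in wild type replicate 2, Eno3 at 5.62 in mutant replicate 2, Plagl1 at 8.38 in mutant replicate 1 and Fst at 1.89 in wild type replicate 4.

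The control probe sets below, outside the comparison, read above the highest wild type array on some mutant arrays but none of them on all 4. Gapdh at the 3 prime end read 879 in mutant replicate 1, under the lowest wild type value of 978.7. Spike-in controls reached 945.73 for BioB, 2718 for BioC, 8104.3 for BioD and 24848 for Cre in mutant replicate 1, against wild type maxima of 172.3, 572.56, 1819.2 and 6829.8. Actin at the 3 prime end reached 7343.7 and Gapdh 2403.3 in mutant replicate 3, 18S rRNA 9221.2 in mutant replicate 2 and the B2 repeat 33763 in mutant replicate 1. The ratio of 3 prime to 5 prime signal was 17.9 ± 2.18 in wild type and 9.96 ± 4.79 in mutant samples for actin and 9.09 ± 0.708 and 6.92 ± 0.308 for Gapdh (SD, n = 4 each; exact permutation p = 0.0286 and adjusted p = 0.214 over 15 measures for each).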

How the results depend on the processing

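The fits without mutant replicates 3 and 4 and without mutant replicates 1 and 2 were chosen only after the result was seen. All 1478 changes kept their direction in every fit that included them, as did the 79 named genes that passed besides Smarca4. Where the groups did not overlap, as for 1462 of the 1478, leaving samples out could not turn a direction. Dim probe sets, near the background bound, limit the log2 changes. The cause of the shifts below was not tested.

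The count of changed probe sets moved to 11486 with array weights (5099 higher, 6387 lower), to 9358 without mutant replicates 1 and 2 (4126 and 5232), and over single left-out samples from 73 to 2926 (higher 40 to 1411, lower 33 to 1515). Over the latter Smarca4 (BRG1) ranged from -1.42 to -1.10. The count of called marker lists was 0 with quantile normalization, the upper 30% filter, an estimated correlation and without mutant replicates 3 and 4, and 0 to 2 over single left-out samples. The count of called gene lists was 0 with an estimated correlation.

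No pairing by replicate number was seen: deviations of same-numbered samples correlated at 0.0242, -0.177, -0.129 and -0.0869, and 1 of 8 samples correlated best with its own number. Only equal numbers were compared, which cannot exclude a collection or processing shared by replicates 1 and 2 or by 3 and 4. Wild type replicates 1 and 2 correlated at 0.948 and 3 and 4 at 0.969, against 0.916 to 0.941 between these pairs. Medians of the cytosolic ribosomal protein list, relative to the wild type mean, were 0.25, 0.155, -0.205 and -0.214 in wild type replicates 1 to 4. With the replicate block 15 probe sets passed (10 higher, 5 lower), and Smarca4 (BRG1) stayed at -1.26 (limma adjusted p = 0.0693).

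Directions of genes that had not passed turned as follows. The second Smarca4 probe set read -0.0174 with quantile normalization, -0.0600 with median centring, -0.108 with 75th percentile centring and -0.00441 with array weights. Smarca2 read -0.0425 with 75th percentile centring, -0.57 with array weights, where it passed (limma adjusted p = 0.0472), and -0.50 without mutant replicates 1 and 2. Zp3 read 0.0493 and Dppa3 -0.26 with quantile normalization, and Dppa3 -0.22 with array weights and -0.30 without mutant replicates 1 and 2. Without mutant replicates 3 and 4, Pou5f1 read 0.44, Hspa1b 0.33, Zp3 0.41, Acr 0.0907, Cd52 -0.38 and Upk1a 0.0387. Cldn3 read -0.0616 with array weights and -0.42 without mutant replicates 1 and 2. Over single left-out samples the second Smarca4 probe set ran from -0.23 to 0.31, Smarca2 from -0.15 to 0.34, Pou5f1 from -0.50 to 0.0414, Hspa1b from -0.42 to 0.0152, Zp3 from -0.17 to 0.17, Dppa3 from -0.00272 to 0.41, Cldn3 from -0.0405 to 0.77 and Upk1a from -0.22 to 0.00331. Of the named genes that had not passed, 24 gained a call with 1 sample left out, 17 without mutant replicate 1 and 16 without mutant replicate 2.

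Among lists, translation factors turned with quantile normalization (camera adjusted p = 0.833), the upper 30% filter (0.792), array weights (0.0943), without _x_at and _s_at probe sets (0.926), and without mutant replicates 1 and 2 (0.0349). They also turned in 2 of the 8 fits with 1 sample left out, without mutant replicate 1 (0.895) and 2 (0.226), in a range of 0.226 to 0.972 over all 8. Pre-mRNA splicing turned with array weights (0.420), without mutant replicates 1 and 2 (0.338) and, of the 8 fits, only without mutant replicate 2 (0.588, in a range of 0.109 to 0.588). Oocyte transcripts turned likewise (0.114, 0.0910 and 0.903, in a range of 0.0201 to 0.903 whose low end kept the direction), and oviduct markers without _x_at and _s_at probe sets (0.908). Without mutant replicates 3 and 4, early 2-cell transcripts, pluripotency and granulosa markers turned (0.897 each), as did cytosolic ribosomal proteins (0.301), the proteasome (0.0162), and oxidative phosphorylation and glycolysis (0.269 each). Of these, cytosolic ribosomal proteins, oxidative phosphorylation and granulosa markers had been called. Over all alternatives the adjusted p ran from 0.00427 to 0.990 for translation factors, 0.00226 to 0.763 for splicing and 7.86e-06 to 0.903 for oocyte transcripts.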

Other observations

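The genes in this part were chosen after their values were seen, and no test of them between the study's groups is given. Mutant replicates 3 and 4 lay above all 6 other arrays for 2382 of 11934 genes (20.0%) and below them for 3080 (25.8%), where chance gives 3.57% per side. For 302 genes the gap was over 2 log2 units upward, among them the calcium-binding protein gene S100a6 (signal at least 3500 against at most 25.2 in the others), the collagen-processing gene Pcolce (4110 against 71.5), the annexin gene Anxa1 (2930 against 55), the caveolin gene Cav1 (2090 against 57.1) and Akr1c18, a progesterone-metabolizing enzyme (1650 against 59.7). The gap was over 2 log2 units downward for 11 genes, and the widest was that of Slc14a1, a urea transporter, which read at most 24.5 against at least 419.

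Mutant replicates 1 and 2 lay above all 6 other arrays for 1583 genes (13.3%) and below them for 756 (6.33%). The gap was over 2 log2 units upward for 0 genes, with 1.94 for the carbonic anhydrase gene Car6 and 1.88 for Ddit3, a transcription factor of the unfolded protein response. Downward it was over 2 for 7: Prss35 (signal at most 2.6 against at least 33.8 in the others), Ptpn23 (11.6 against 89.6), Gm6607, Sh3bp5l, Pygb, Hs1bp3 and Mrpl58. All 7 lay under the background bound on both mutant replicates 1 and 2 (27.0 and 37.7), so the size of their gaps is uncertain.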
